A study of Harpegnathos saltator with 27 samples.

How the data were processed

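RNA was sequenced from the ovary, the fat body of the abdomen and the brain without its visual part, in Harpegnathos saltator workers injected with solvent, methoprene or 20E, with 3 libraries per tissue and treatment. Per the labels' protocols, libraries were made with a poly(A) kit and sequenced on an Illumina HiSeq. The deposited values are whole-number read counts per gene for 20659 gene identifiers, made by the authors with Trimmomatic, STAR 2.5.3a and HTSeq per the submitters' processing notes. The genome build, the annotation and the strand setting are not given in the sources used here. Reads of overlapping or antisense genes may therefore be mixed, and genes with a near-identical copy lose the reads that align to several places.

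The table also carries the 5 summary lines that HTSeq writes, which were kept out of library sizes and tests. Reads outside any gene took 48.5 to 54.2% of the table's total in brain, 26.2 to 32.2% in fat body and 35.0 to 38.6% in ovary. Reads that aligned to several places took 6.58 to 18.5%, and reads that matched more than 1 gene took 0.564 to 2.25%. Gene counts ran from 8.74 to 21.6 M (mega) per library. No pair of replicates agreed within sampling noise, since the lowest chi-square per degree of freedom of a pair was 7.94. Each treatment's libraries come from 3 ants, per the series' design, so the p-values of the fits per tissue measure the spread between ants. The fit of all 27 libraries treated the tissues of an ant as independent, so its p-values mix spread within and between ants.

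Of the 20659 identifiers, 0 were found in a table of 14329 annotated genes of the species, and none carries a name in the count table. The gene lists, hormone response genes and cell type markers fixed before the data were examined were therefore not tested. By the fixed rule, up to 2 genes that rose and 2 that fell are named per comparison. For tissue comparisons they are those with the largest fold change among genes with an adjusted p under 0.05, a mean of at least 2 CPM and no overlap between groups, or, where fewer than 5 genes passed, those with the smallest p, given as values that did not pass. For differences between tissues they are those with the smallest adjusted p. The 18 genes shared by brain and fat body were examined after the calls were seen.

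Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM normalization, filterByExpr, robust glmQLFit and glmQLFTest). One fit was made per tissue over its 9 libraries, with 12379 genes in brain, 9870 in fat body and 11418 in ovary, and without a replicate block. One fit over all 27 libraries gave the differences between tissues over 13367 genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors are those implied by the F statistic, and CPM values use the TMM library sizes. Gene sets were tested with camera of limma 3.58.1 on voom values with a preset correlation of 0.01, with an estimated correlation, and with fry. There were 12 set tests across tissues, 18 set tests of tissue-enriched genes and 18 Fisher's exact tests of tissue-enriched genes with any call, each family adjusted on its own. Tissue-enriched genes were at least 8-fold above each other tissue in 1 treatment, with a test against a 2-fold floor; shares of counts per library use those enriched in all 3 treatments (1031 in brain, 365 in fat body, 232 in ovary). The effect of shared solvent libraries was simulated 20 times per tissue with unchanged groups, all drawn from 1 dispersion per gene.

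The scripts were tested on simulated counts drawn from the brain, fat body and ovary means and library sizes and from edgeR's dispersion of each gene. The simulated libraries varied independently and none stood apart. The rates below hold for that model, which is edgeR's own. They need not hold for the real ovary libraries, of which 2 stood apart, and do not show that large ovary changes were absent. The edgeR test recovered 44.8% of 2-fold changes in brain, 8.96% in fat body and 34.3% in ovary, and 84.8%, 83.3% and 83.3% of 4-fold changes. Of its calls 3.26%, 6.06% and 3.57% were false, against 23.8%, 22.5% and 31.6% of DESeq2's. For limma voom with library weights 4.55%, 4.92% and 3.61% were false. The simulated 4-fold differences between brain and fat body were recovered in 80.0% of genes. They were drawn with the same dispersion of a gene in all tissues, so they cannot show the effect of a spread that differs between tissues.

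Before the data were examined, these alternatives were fixed: DESeq2 1.42.0, its size factors in edgeR, no filter on low counts, the replicate number as a block, only the 2 groups compared, limma voom with library weights, a random term per presumed ant for the differences between tissues, and leaving out each library in turn. Removing 4 libraries that stood apart in brain and ovary was added after the data were seen. So were the removal of each pair of ovary libraries and a fixed term per presumed ant. Brain EtOH replicate 3, brain JHA replicate 1 and ovary JHA replicate 1 stood apart on the first principal component of their tissue. Ovary 20E replicate 3 stood apart on the second, at 49.2. In brain, 20E replicates 2 and 3 lay at the other end of the first component and were kept.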

Results

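The data were gene counts from RNA sequencing of 27 libraries of the ant Harpegnathos saltator, a species whose workers can change caste as adults. Workers were injected in the abdomen with 500 ng of methoprene, a synthetic juvenile hormone analog (JHA), with 500 ng of 20-hydroxyecdysone (20E), the active insect ecdysteroid, or with about 1 µL of the 10% ethanol solvent (EtOH). The non-visual part of the brain, the abdominal fat body and the ovary were taken 12 hours later, with 3 libraries for each of the 9 combinations of tissue and treatment. Each library held between 8.74 and 21.6 M (mega) counts on genes, with medians of 11.2 M in brain, 15.8 M in fat body and 12.7 M in ovary. The 10 most abundant genes of a library took 25.1 to 33.0% of its gene counts in fat body, 5.25 to 6.35% in brain and 3.75 to 4.88% in ovary. Genes are given by the identifiers of the table, which pairs none of its 20659 identifiers with a name, so no pathway or function is stated for any of them.

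The first question was which genes each hormone changed in each tissue relative to solvent. With edgeR's quasi-likelihood test and a Benjamini-Hochberg adjusted p under 0.05, 20E changed 231 genes in brain and 100 in fat body, and JHA changed 111 genes in fat body. No gene passed for JHA in brain or for either hormone in ovary. Every gene that passed had no overlap between the 3 values of one group and the 3 of the other, a separation that chance gives to 10% of genes in one comparison of 3 against 3.

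**Figure D1:**
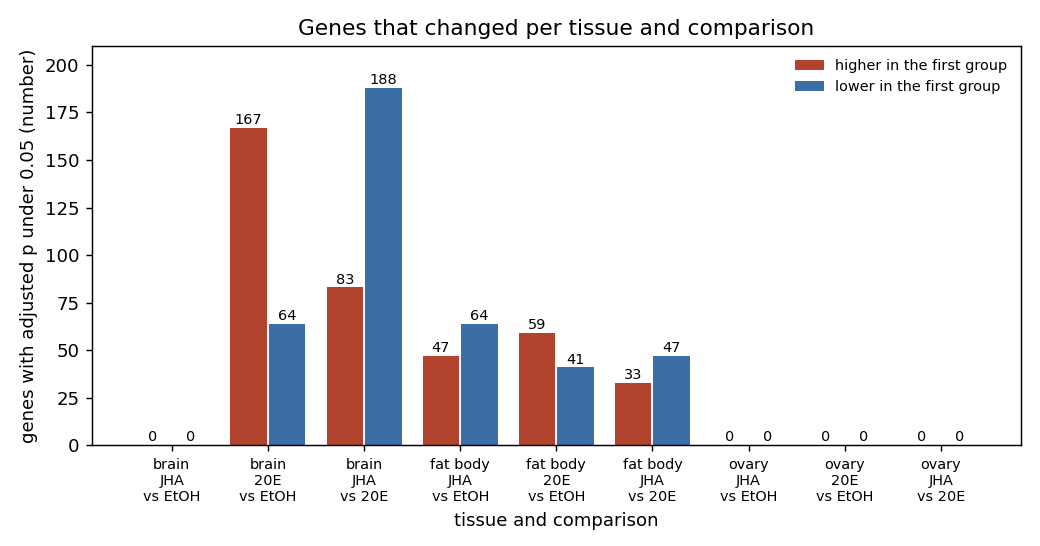
Number of genes with an adjusted p under 0.05 (edgeR quasi-likelihood test, y axis) in each tissue and comparison (x axis), with separate bars for genes higher and lower in the first-named group. The tallest bars are the 188 genes lower with JHA than with 20E and the 167 genes higher with 20E than with solvent, both in brain, and all 6 ovary bars stand at 0.

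In brain, 20E was followed by more rises than falls, with 167 genes higher and 64 lower among 12379 tested. The median log2 fold change was 1.46 among the genes that rose and -1.02 among those that fell, and 51 of the 231 changed at least 4-fold. By the naming rule, the genes with the largest rises were HSALG025031.1, which went from 0.295 ± 0.361 to 34.0 ± 20.1 CPM (counts scaled to library size; mean ± SD, n = 3), and HSALG005121.2, from 1.82 ± 0.565 to 101 ± 75.1 CPM. Their log2 fold changes were 6.82 (SE 0.79, adjusted p = 0.00342) and 5.80 (SE 0.81, adjusted p = 0.00987), and the calls were lost in 0 and 4 of 13 alternative fits. In 20E replicate 1, HSALG005121.2 stood at 14.7 CPM, against 136 and 152 CPM in replicates 2 and 3. HSALG028135.1 fell by 2.30 and HSALG006313.2 fell by 2.25 on the log2 scale (adjusted p = 0.0237 and 0.0246), the latter from 8.82 ± 3.30 to 1.85 ± 1.00 CPM, and these 2 calls were lost in 7 and 6 of 13 alternative fits. Leaving out any single library of the 6 compared moved the count by more than 1.5 times, to 53, 70 or 87 without EtOH replicate 1, 2 or 3, and to 423, 51 or 57 without 20E replicate 1, 2 or 3. EtOH replicate 3 and JHA replicate 1 stood apart on the first principal component of brain, at 42.0 and 47.7. At its other end lay 20E replicates 2 and 3, at -34.3 and -33.4, with the remaining libraries between -12.1 and 0.525. Without EtOH replicate 3 and JHA replicate 1, 400 genes passed (188 higher, 212 lower), 169 of them among the 231. The 20E libraries were kept, and removing only the opposite end can by itself widen the difference between 20E and solvent.

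For JHA in brain no gene passed, although HSALG003795.2 came close. It stood at 181 ± 118 CPM with JHA and 14.3 ± 2.40 CPM with solvent (SD, n = 3), a log2 difference of 3.66 (SE 0.40, adjusted p = 0.0681), and each JHA library, at 112 CPM or more, lay above the highest solvent library, at 17.1 CPM. HSALG027514.1 was at 28.9 ± 23.6 against 1.72 ± 0.672 CPM (adjusted p = 0.287). HSALG000386.2 was at 95.8 ± 8.23 against 169 ± 8.30 CPM (adjusted p = 0.27) and HSALG000619.2 at 9.06 ± 1.07 against 33.4 ± 14.5 CPM (adjusted p = 0.287). HSALG003795.2 passed in 6 of 13 alternative fits and each of the other 3 in 2 of 13. An unadjusted p under 0.05 was reached by 398 of 12379 genes, where 619 would be expected by chance; it was 1743 with library weights in limma voom and 691 without the 2 brain libraries that stood apart. DESeq2's Wald test called 30 genes on the same libraries and limma voom with library weights called 33. With edgeR, 1, 3 or 1 genes passed without JHA replicate 1, 2 or 3, and 1 passed without the 2 brain libraries that stood apart.

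Set directly against each other in brain, the hormones differed in 271 genes, 83 of them higher with JHA and 188 higher with 20E. HSALG025031.1 and HSALG005121.2 again differed most, at 0.295 ± 0.201 and 1.63 ± 0.263 CPM with JHA, with log2 fold changes against 20E of -6.77 and -5.96 (adjusted p = 0.00434 and 0.0084; lost in 1 and 2 of 13 alternative fits). HSALG017235.2 was higher with JHA, at 32.8 ± 10.2 against 2.42 ± 2.06 CPM (log2 fold change 3.78, adjusted p = 0.0399), as was HSALG027514.1 (3.23, adjusted p = 0.0237). These 2 calls were lost in 10 and 4 of 13 alternative fits. HSALG003795.2 was 8.21-fold higher with JHA than with 20E (adjusted p = 0.00603). Without 20E replicate 1, 2 or 3 the count was 484, 74 or 78, and without JHA replicate 1, 2 or 3 it was 147, 123 or 89. Without the 2 brain libraries that stood apart it was 423. The share higher with JHA, 30.6% of the 271, was 45.2% of those 423, 48.5% of 1705 with library weights in limma voom, and 13.5 to 41.7% with 1 library left out.

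In fat body, JHA changed 111 of 9870 genes, 47 higher and 64 lower. HSALG004351.1 rose from 0.445 ± 0.260 to 24.7 ± 9.84 CPM (log2 fold change 5.74, SE 1.04, adjusted p = 0.0451) and HSALG000750.2 from 0.418 ± 0.294 to 18.3 ± 4.93 CPM (5.39, SE 0.54, adjusted p = 0.0103). These 2 calls were lost in 8 and 0 of 12 alternative fits. HSALG007590.2 fell from 101 ± 11.8 to 3.49 ± 2.43 CPM (-4.84, SE 0.73, adjusted p = 0.0255). HSALG000622.2 fell from 360 ± 285 to 15.8 ± 4.15 CPM (-4.51, SE 0.68, adjusted p = 0.0254). The calls of these 2 were lost in 5 and 3 of 12 alternative fits. In brain, HSALG000622.2 stood at 63.2 ± 4.74 with JHA and 67.7 ± 4.18 CPM with solvent and did not pass. The count rested on single libraries, falling to 4 without JHA replicate 3, 18 without JHA replicate 1, 48 without JHA replicate 2, 58 without EtOH replicate 2 and 48 without EtOH replicate 3. The share of higher genes, 42.3% of the 111, ran from 31.0 to 61.1% with 1 library left out.

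With 20E, 100 fat body genes changed, 59 higher and 41 lower. HSALG001741.2 rose 29.3-fold, from 2.19 ± 0.398 to 64.3 ± 2.28 CPM (log2 fold change 4.87, SE 0.36, adjusted p = 0.00198), with the 3 hormone libraries between 61.9 and 66.4 CPM. HSALG030197.1 rose from 0.590 ± 0.331 to 18.5 ± 5.84 CPM (4.97, SE 0.53, adjusted p = 0.00739). These 2 calls were lost in 0 and 1 of 12 alternative fits. HSALG012049.2 fell from 304 ± 98.9 to 33.4 ± 15.1 CPM (-3.19, SE 0.50, adjusted p = 0.0287), and HSALG011991.1 from 10.6 ± 5.25 to 1.75 ± 0.419 CPM (-2.60, SE 0.49, adjusted p = 0.0483), calls that were lost in 5 and 9 of 12 alternative fits. The count was 13, 35 or 26 without EtOH replicate 1, 2 or 3, and 32 or 33 without 20E replicate 2 or 3. It was 33 in a fit of the 6 libraries alone. The share of higher genes, 59% of the 100, was 45.2% of 524 with DESeq2 and 42.9 to 75% with 1 library left out.

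Set against 20E, JHA differed in 80 fat body genes, 33 higher and 47 lower. HSALG000750.2 was 20.1-fold higher with JHA, since it stood at 0.905 ± 0.508 CPM with 20E (adjusted p = 0.0122), and HSALG009400.2 was at 297 ± 43.7 against 27 ± 11.5 CPM (log2 fold change 3.46, adjusted p = 0.0122), each call lost in 1 of 12 alternative fits. HSALG001561.2 was lower with JHA, at 11.7 ± 3.60 against 510 ± 425 CPM (-5.45, adjusted p = 0.019), as was HSALG004952.1, at 0.371 ± 0.306 against 13.8 ± 10.6 CPM (-5.20, adjusted p = 0.0358). These 2 calls were lost in 3 and 9 of 12 alternative fits. The count fell to 1, 16 or 10 without JHA replicate 1, 2 or 3 and to 37 without 20E replicate 3.

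**Figure D2:**
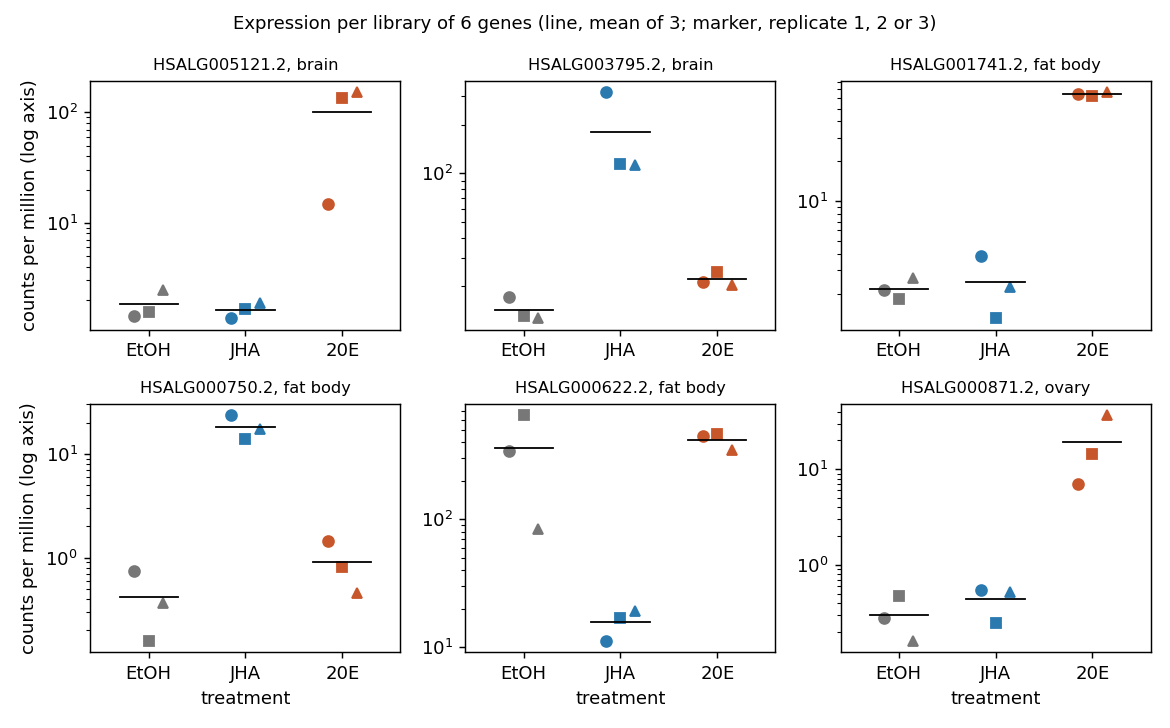
Library-scaled counts (CPM, y axis, log scale) of 6 genes in the tissue named above each panel, by treatment (x axis), with 1 point per library, its shape the replicate number, and a line at the mean of 3. HSALG001741.2 lies between 61.9 and 66.4 CPM in the 3 fat body libraries with 20E, and HSALG000622.2 lies at 19.2 CPM or less in the 3 with JHA, below all solvent and 20E libraries.

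The calls for JHA and 20E in fat body were also set side by side. Of the genes called, 5 were higher with both hormones and 16 lower with both, where independent lists would share 0.281 and 0.266, and 0 moved in opposite directions. Both comparisons share the 3 solvent libraries, which alone bring such values above 0. In simulated unchanged groups against those libraries at most 1 gene was called in both. That value leaves out real effects, so how many of the 5 and 16 come from the sharing stays open. In the same simulations the correlation of log2 fold changes across genes averaged 0.507, close to the observed 0.529. The observed covariance was 0.252 against a simulated 0.111. In brain and ovary the covariances, 0.042 and 0.0445, lay below the simulated 0.0649 and 0.096, and the correlations were 0.242 and 0.257. The simulations gave the 3 treatments 1 dispersion per gene, while the effect of sharing depends on the spread of the solvent libraries. In ovary, solvent pairs had a chi-square per degree of freedom of 10.6 to 19.1, and pairs with a library that stood apart 96.2 to 161. The simulated covariance may thus be too high in ovary, and may be off in the other tissues. With 3 solvent libraries the controls were not split, so the part of the fat body covariance that comes from sharing them was estimated by simulation alone.

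In ovary, no gene passed for JHA, for 20E or for the direct comparison among 11418 tested. The largest difference under 20E among the named genes was that of HSALG000871.2, at 19.4 ± 15.5 CPM with 20E and 0.304 ± 0.157 CPM with solvent (log2 difference 5.95, SE 0.74, adjusted p = 0.273). This gene passed in both other tissues, with log2 fold changes of 3.13 in brain and 2.80 in fat body. HSALG006566.2 was at 69.6 ± 21.8 with 20E against 20.5 ± 3.97 CPM with solvent (adjusted p = 0.367) and 15.9 ± 2.21 CPM with JHA (adjusted p = 0.136 between the hormones). HSALG007975.2 and HSALG006613.2 had log2 differences of -1.51 and -1.21 under 20E (adjusted p = 0.548 for both). Of these 20E differences from solvent, that of HSALG000871.2 passed in 5 of 13 alternative fits, that of HSALG006566.2 in 4, and the other 2 in 3 each. For JHA, HSALG010831.1 was at 418 ± 40.1 against 48.2 ± 48.8 CPM and HSALG010835.1 at 182 ± 18.4 against 21.5 ± 24.3 CPM, while HSALG001069.2 was at 71.2 ± 9.99 against 120 ± 14 CPM and HSALG006549.2 at 1.03 ± 0.314 against 3.80 ± 0.868 CPM (adjusted p = 0.825 for all 4, each passing in 1 of 13 alternative fits). Between the hormones, HSALG004093.1 (3.80, adjusted p = 0.371) and HSALG009402.1 (1.09, adjusted p = 0.383) were nominally higher with JHA and HSALG021601.1 (-2.53, adjusted p = 0.136) lower. The first 2 passed in 1 of 13 alternative fits each, and HSALG021601.1 and HSALG006566.2 in 3.

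These 0 counts came with 401, 274 and 481 genes at an unadjusted p under 0.05 for JHA, 20E and JHA against 20E, where 571 would be expected by chance. With library weights in limma voom these were 1334, 2412 and 988. DESeq2's Wald test called 7, 38 and 60 genes, and limma voom with library weights called 0 for JHA, 41 higher and 266 lower for 20E, and 5 between the hormones. JHA replicate 1 and 20E replicate 3 stood apart from the other ovary libraries. Genes enriched in ovary took 2.91% and 3.54% of their gene counts and 5.14 to 6.35% in the other 7 libraries, and genes enriched in fat body took 2.74% and 2.63% against 1.63 to 2.03%. Without both of these libraries, 370 genes passed for 20E (113 higher, 257 lower), 1 for JHA and 8 between the hormones, and 1111 (JHA), 2655 (20E) and 960 (JHA against 20E) had an unadjusted p under 0.05. Without 20E replicate 1 alone, 3 genes passed for 20E and 3 between the hormones. The other 8 ways of removing 1 JHA and 1 20E library gave at most 5 genes for 20E. JHA replicate 1 belongs to neither group of the 20E comparison with solvent and acts on it only through the shared fit. On the first principal component of ovary, 20E replicate 3 lay at -25.5. Solvent libraries lay between -4.12 and 16.1, and 20E replicates 1 and 2 at 32.7 and 27.3. Removing a 20E library beyond solvent can by itself widen the difference between 20E and solvent, though without it alone 0 genes passed for 20E.

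**Figure D3:**
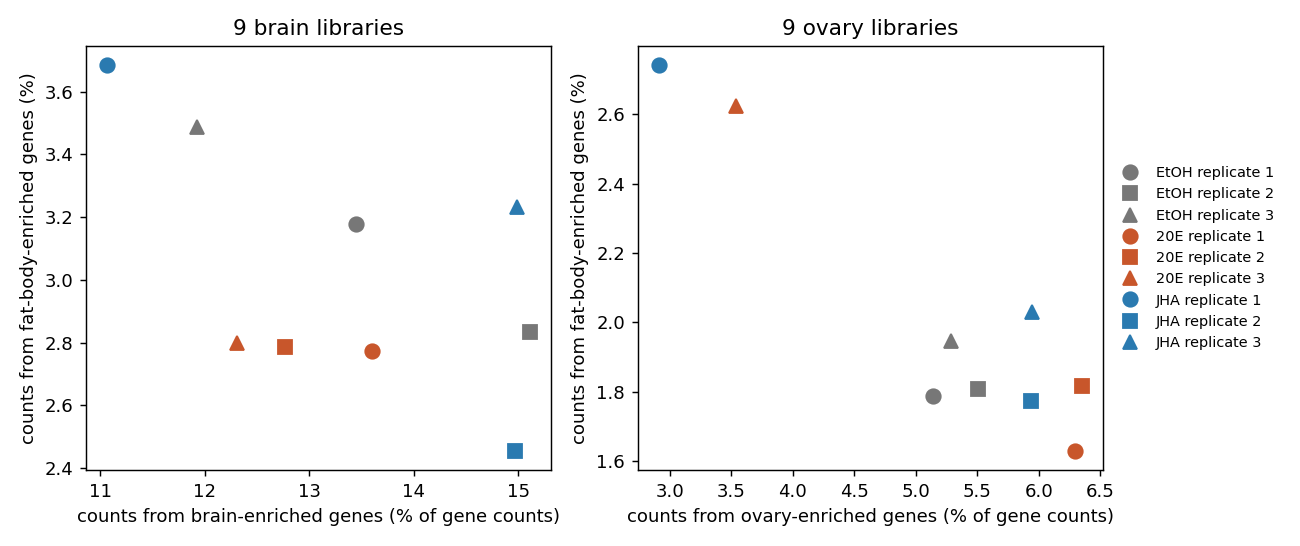
Share of each library's gene counts from genes enriched in fat body (y axis, %) against the share from genes enriched in the library's own tissue (x axis, %), for the brain libraries (left) and the ovary libraries (right), colored by treatment, with the replicate number as the marker shape; the axes do not start at 0. In ovary, JHA replicate 1 (2.91%) and 20E replicate 3 (3.54%) lie apart from the other 7 libraries (5.14 to 6.35%), and in brain JHA replicate 1 (11.1%) and EtOH replicate 3 (11.9%) have the lowest shares of brain-enriched genes.

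The next question was whether a hormone changed the same genes in different tissues. Under 20E, 18 genes passed in both brain and fat body, all with the same sign. The 14 that rose in both compare with 0.764 expected by chance (Fisher's exact test, p = 1.36e-14) and the 4 that fell in both with 0.226 (p = 7.19e-05). HSALG013686.2 and HSALG015071.2 rose by 3.41 and 3.45 log2 units in brain and by 3.36 and 3.22 in fat body, HSALG001741.2 by 1.77 and 4.87. Among the 4 that fell were HSALG006313.2 (-2.25 in brain, -1.80 in fat body) and HSALG012347.2 (-1.43 and -2.18). Of the 18, 14 had the larger fold change in fat body. This can follow from the selection, since mostly large changes passed there. The median log2 fold change of all called rises was 2.44 in fat body and 1.46 in brain. None of the 18 passed in ovary, where 13 had the same sign and 5 an unadjusted p under 0.05. When 1 replicate number was left out of both tissues, the number that still passed in both was 4 without EtOH number 1, 2 or 3 or without 20E number 2, 5 without 20E number 3 and 15 without 20E number 1.

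The 64 genes that fell in brain under 20E were also tested as a group in the other tissues. Of the 53 measured in fat body 45 were below 0, with a median of -0.51 (camera, adjusted p = 1.74e-08, and adjusted p = 0.00269 with an estimated correlation), and of the 56 measured in ovary 39 were below 0, with a median of -0.20 (adjusted p = 1.74e-08, and 0.00269 with an estimated correlation). The genes that rose in fat body had a median of 0.47 in brain, with 46 of 56 above 0 (adjusted p = 3.34e-15, and 0.0118 with an estimated correlation). Those that rose in brain had a median of 0.61 in fat body (adjusted p = 1.08e-12, 0.0659 with an estimated correlation and 0.0147 with fry). Those that fell in fat body had a median of -0.28 in brain (adjusted p = 1.74e-08, 0.0693 with an estimated correlation and 0.0191 with fry). For JHA, the 62 of the 64 genes lower in fat body that were measured in brain had a median of -0.09 there (adjusted p = 0.0179, and 0.193 with an estimated correlation). The 59 of these lower genes measured in ovary had a median of -0.02 there, with 31 below 0 (camera, adjusted p = 0.58). The 44 measured of those higher in fat body had medians of -0.03 in brain (adjusted p = 0.677) and -0.12 in ovary (adjusted p = 0.0179, and 0.269 with an estimated correlation). In ovary, the genes that rose with 20E had medians of 0.13 (brain) and 0.09 (fat body) and those that fell in fat body -0.26. These calls were lost with an estimated correlation (adjusted p = 0.303, 0.303 and 0.29) and with fry (adjusted p = 0.501, 0.506 and 0.332). The smallest adjusted p of a JHA set with fry was 0.162. The tissues of a treatment came from the same 3 ants, and neither these set tests nor Fisher's test on shared genes takes that into account.

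**Figure D4:**
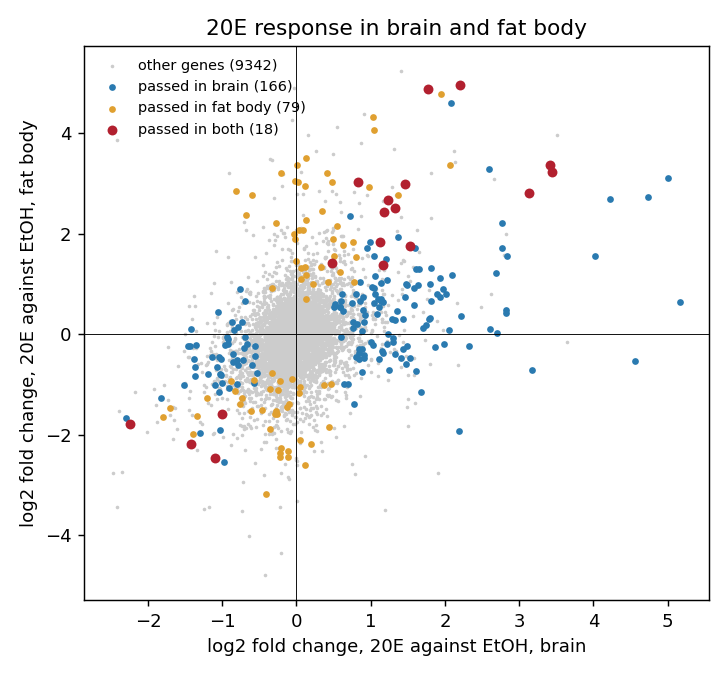
Log2 fold change of 20E against solvent in brain (x axis) and fat body (y axis), with 1 point per gene measured in both tissues, colored by the tissue in which it passed an adjusted p of 0.05. The 18 genes that passed in both lie in the upper right (14) or lower left (4), while 166 passed in brain alone and 79 in fat body alone.

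Differences between tissues were tested directly as interactions in a fit of all 27 libraries and 13367 genes. This fit treated the tissues of an ant as independent. It also gave each gene 1 dispersion for all tissues. In the fits per tissue the common biological coefficient of variation was 0.322 in fat body, 0.307 in ovary and 0.223 in brain. The p-values of differences that involve the tissues with the larger spread, fat body above all, may therefore be too small, which was not tested. The JHA effect differed between brain and fat body for 94 genes and between fat body and ovary for 193, and between brain and ovary for 0 by edgeR (about 3.0e+02 at an unadjusted p under 0.05, and 2 by DESeq2). HSALG029765.1 and HSALG009158.1 rose with JHA in fat body by 2.04 and 2.00 log2 units, against -0.03 and -0.12 in brain and -0.13 and -0.14 in ovary, with adjusted p of 0.000424 for both differences from brain and of 0.000114 and 0.000153 for those from ovary. HSALG002473.2 was at -3.48 in fat body and 0.21 in brain (adjusted p = 0.000615), and HSALG002887.2 at -1.81 and 0.10 (adjusted p = 0.000635). HSALG002447.2 was at -1.81 in fat body and 0.52 in ovary (adjusted p = 0.000114) and HSALG009446.1 at -1.66 and 0.12 (adjusted p = 0.000153). The count of 94 was 55 or 49 without brain EtOH replicate 1 or 2 and 52 or 60 without brain JHA replicate 1 or 2. The count of 193 was 301 or 120 without fat body EtOH replicate 1 or 3, 96 without fat body JHA replicate 3, 95, 78 or 96 without ovary EtOH replicate 1, 2 or 3, and 117 without ovary JHA replicate 1.

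The 20E effect differed for 53 genes between brain and fat body, for 80 between fat body and ovary and for 3 between brain and ovary. The last count was 11 with a random term per presumed ant and 10 with a fixed term. Between brain and fat body, HSALG006968.1 was at 0.01 and 3.37 log2 units (adjusted p = 0.00225) and HSALG001741.2 at 1.77 and 4.87 (adjusted p = 0.00225), whereas HSALG002574.2 was at 0.20 and -2.19 and HSALG013102.2 at 0.88 and -0.76 (adjusted p = 0.00288 for both). HSALG013686.2 and HSALG015071.2, which rose in brain, were at 0.19 and 0.24 in ovary (adjusted p = 0.000588 for both differences); the third gene, HSALG008396.2, named after its values were seen, had a difference of 2.32 (adjusted p = 0.0378). Between fat body and ovary, HSALG030197.1 was at 4.97 and -0.52 (adjusted p = 0.000269) and HSALG007563.2 at 2.51 and 0.00 (adjusted p = 7.29e-05), and HSALG009122.1 and HSALG009116.1 were at -2.37 and -2.45 in fat body and near 0 in ovary (adjusted p = 0.000702 and 0.00116). Without the 4 libraries that stood apart these counts were 110, 240 and 10, in the same order of pairs. The count of 53 was 27, 31 or 30 without brain EtOH replicate 1, 2 or 3, 26 or 25 without brain 20E replicate 2 or 3, and 93 without fat body 20E replicate 1. The count of 80 was 139 or 50 without fat body 20E replicate 1 or 3, 40, 44 or 47 without ovary EtOH replicate 1, 2 or 3, and 42 or 43 without ovary 20E replicate 1 or 2, and the count of 3 was 13 without brain 20E replicate 1.

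Genes enriched in a tissue, taken as those at least 8-fold above each other tissue in the treatment left out of a comparison, were tested for over-representation among the genes called. The test was made for rises and falls in fat body and for 20E in brain, since no gene was called for JHA in brain or in ovary. In fat body, 11 of the 64 genes that fell with JHA were fat-body-enriched (17.2%, against 4.81% of genes tested; Fisher's exact test, adjusted p = 0.00377) and 7 of the 41 that fell with 20E (17.1% against 4.96%; adjusted p = 0.0284). Both lists of falls rest on the same 3 solvent libraries and have 16 genes in common, so these are not 2 independent results. Of the genes that rose there, 4 of 47 with JHA (adjusted p = 0.737) and 2 of 59 with 20E (adjusted p = 1) were fat-body-enriched, and 3 of the 59 were ovary-enriched (adjusted p = 0.0826). In brain, 14 of the 64 genes that fell with 20E were brain-enriched (21.9% against 9.94%; adjusted p = 0.0284), as were 9 of the 167 that rose (5.39%; adjusted p = 0.149). Fat-body-enriched genes were 6 of the 64 that fell (9.38% against 3.38%; adjusted p = 0.0826). As a set they had a median of -0.14 with 20E in brain (adjusted p = 0.0205, and adjusted p = 0.971 with an estimated correlation), and they took 2.77 to 2.80% of counts in the brain libraries with 20E, 2.83 to 3.49% with solvent and 2.45 to 3.68% with JHA. The brain-enriched genes took 11.9% of counts in EtOH replicate 3 and 11.1% in JHA replicate 1 against 12.3 to 15.1% in the other brain libraries. The brain-enriched genes as a set had a median of -0.02 with 20E in brain (adjusted p = 0.861). The 490 fat-body-enriched genes measured in fat body had a median log2 fold change of -0.30 with 20E, and 341 of them were below 0 (camera, adjusted p = 4.42e-05, and adjusted p = 0.296 with an estimated correlation). Of the 252 brain-enriched genes measured in fat body 165 were below 0 too, with a median of -0.29 (adjusted p = 0.0254, and adjusted p = 0.971 with an estimated correlation). With JHA the medians in fat body were -0.15 for fat-body-enriched genes (adjusted p = 0.114) and -0.29 for brain-enriched genes (adjusted p = 0.0801). Of the 18 set tests of enriched genes, 6 passed with the preset correlation and 0 with an estimated one. With fry, only the fat-body-enriched genes under 20E in fat body passed (adjusted p = 0.0484). These groups were chosen after the data were seen, and Fisher's test treats genes as independent.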

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

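The permutation counts below were planned before their results were seen; the reads at several places were looked at after the other results. Differences between tissues in the response to a hormone were called for 94 genes (JHA, brain against fat body), 193 (JHA, fat body against ovary), 53 (20E, brain against fat body), 80 (20E, fat body against ovary) and 3 (20E, brain against ovary). For JHA between brain and ovary there were 0. In 24 drawn permutations of the treatment labels within each tissue, as many genes were called in 3 of 24 permutations for JHA between brain and fat body (highest other 224), 2 of 24 for JHA between fat body and ovary (highest other 200), 3 of 24 for 20E between brain and fat body (highest other 167), 2 of 24 for 20E between fat body and ovary (highest other 130) and 3 of 24 for 20E between brain and ovary (highest other 40), the real labels included. These permutations do not exclude chance for any of these 5 results. They shuffled the labels of each tissue separately, so they did not keep together the tissues of 1 ant and are no test of a chance difference between ants. For JHA between brain and ovary, 24 of 24 permutations reach the real count of 0 by construction (highest other 1), which tests nothing.

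The permutations were also divided by whether a tissue kept its real grouping, which was not part of the planned count. In every other permutation that gave as many genes for the 5 nonzero results, at least 1 of the 2 tissues had kept its real grouping, as it was or mirrored, so a difference within that tissue was still present. In the 18 permutations with neither tissue in its real grouping, at most 1 gene was called for JHA between brain and fat body and at most 3 for JHA between fat body and ovary. For 20E the highest counts without a real grouping were 3 in 17 permutations (brain and fat body), 2 in 16 (fat body and ovary) and 0 in 17 (brain and ovary). Within a single tissue, splits other than the real one called at most 1 gene. Low counts were therefore likely in advance for these permutations and do not argue against chance.

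Reads that aligned to several places, which enter no gene count, took 17.9 ± 0.745% of the fat body reads with 20E and 15.6 ± 0.534% with solvent (SD, n = 3), with no overlap between the groups (exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows). In the same comparison, reads outside genes (27.4% against 30.6%) and reads matching more than 1 gene (2.11% against 1.85%) did not overlap either. Of 30 such tests of library measures over tissues and hormones, 5 showed no overlap, where 3 would be expected by chance.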

How the results depend on the processing

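The removal of the 4 libraries that stood apart, the fixed term per presumed ant and the tests of what the replicate numbers share were chosen after the data were seen; the other settings were fixed before. DESeq2's size factors moved no count by more than 1.5 times. In each case below the cause was not tested, except that leaving out libraries or fitting 6 of them uses fewer samples. Counts are in the order JHA against EtOH, 20E against EtOH, JHA against 20E where 3 are given. DESeq2's Wald test called 30, 559 and 597 genes in brain, 624, 524 and 539 in fat body and 7, 38 and 60 in ovary; it kept all 231, 271, 111, 100 and 80 calls of edgeR. For differences between tissues it called 261 (JHA) and 198 (20E) between brain and fat body, 2 and 22 between brain and ovary, and 547 and 243 between fat body and ovary. Library weights in limma voom gave 33, 1584 and 1705 in brain, 198 (JHA) and 66 (20E) in fat body, and 3.1e+02 (20E; 41 higher, 266 lower) and 5 (JHA against 20E) in ovary. Fits of only the 2 groups gave 119 for 20E in brain and 33 for 20E in fat body. Without the filter, 123 genes passed for JHA against 20E in fat body, 1 for 20E and 5 for JHA against 20E in ovary, and 124 for the JHA difference between fat body and ovary. Without the libraries that stood apart the counts were 1, 400 and 423 in brain and 1, 370 and 8 in ovary, and for the 20E differences 110 (brain and fat body), 10 (brain and ovary) and 240 (fat body and ovary). The median of ovary-enriched genes in ovary then went from -0.13 (adjusted p = 0.00108, and 0.971 with an estimated correlation) to 0.07 for JHA (adjusted p = 0.0046, and 0.553) and from -0.02 (adjusted p = 0.19, and 0.971) to 0.08 for 20E (adjusted p = 0.0200, and 0.553), after the 2 libraries with the lowest shares of these genes were removed. That of fat-body-enriched genes under JHA in ovary went from 0.23 (adjusted p = 0.0104, and 0.971) to 0.01 (adjusted p = 0.671, and 0.9), so with estimated correlations neither direction passed. The share of higher genes among the brain 20E calls, 72.3% with all libraries, was 47% in that setting and 50.1% with library weights.

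Leaving out 1 library gave 0 to 3 genes for brain JHA, 51 to 423 for brain 20E, 74 to 484 for brain JHA against 20E, 4 to 82 for fat body JHA, 13 to 105 for fat body 20E, 1 to 120 for fat body JHA against 20E, 0 for ovary JHA, 0 to 3 for ovary 20E and 0 to 3 for ovary JHA against 20E. The differences between tissues ranged from 49 to 119 (JHA) and 25 to 93 (20E) for brain and fat body, 0 (JHA) and 2 to 13 (20E) for brain and ovary, and 78 to 301 (JHA) and 40 to 139 (20E) for fat body and ovary. Of the 54 named gene values, 0 changed sign in any setting. For the calls within a tissue this says little, since these genes were chosen with groups that do not overlap. Leaving out a library then keeps their direction. The other named genes were chosen by the smallest p, which favors a stable sign. Of the 432 values with 1 library left out, 371 stayed on the same side of the threshold, 55 lost the call and 6 gained it. The correlation of the JHA and 20E fold changes was 0.233, 0.496 and 0.235 in brain, fat body and ovary over genes of at least 10 CPM. Lists of named genes, single hormone response genes and their alternatives were not run, since no identifier carries a name. Splits of the 6 libraries of a comparison number 10, too few for a share under 0.05: the real counts were 231, 271, 111, 100 and 80 and the highest of the other splits 0, 0, 0, 1 and 0, while for brain JHA and the ovary comparisons the real count and every other split gave 0. At this depth and spread, 8.96% of 2-fold changes in fat body were recovered in simulation, so smaller changes were mostly not detectable.

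With the replicate number as a block, 77 genes passed for 20E in brain, 132 for JHA against 20E in brain, 52 for 20E in fat body and 5 for the 20E difference between brain and ovary; no other count of the block fits moved by more than 1.5 times. Within a tissue, 9 of 27 correlations of same-numbered libraries of different treatments were over 0.1 (mean -0.0353), but for 20E and JHA in fat body all 3 were (mean 0.233), so a preparation batch for each number stays open. Across tissues of 1 treatment, 25 of 27 same-number correlations were over 0.1 (mean 0.192) and each library correlated best with its own number in 27 of 27 cases, a hint from the data and not from the design. The exact permutation p was 2.14e-05, the smallest the 46656 permutations can give, which is consistent with the hypothesis that the 3 tissues of a number come from 1 ant. RNA passed between libraries of a number was not tested. A random term per presumed ant gave 11 genes and a fixed term 10 for the 20E difference between brain and ovary, against 3. With either term no other count of differences between tissues moved by more than 1.5 times.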

Other observations

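The tests of the ovary libraries were chosen after the result was seen. The genes that passed for 20E in ovary once JHA replicate 1 and 20E replicate 3 were removed can be compared with the other tissues. Of the 113 higher genes, 85 were measured in fat body, where 56 were above 0 with a median log2 fold change of 0.29 (camera p = 5.61e-05, and p = 0.006 with an estimated correlation) and 3 passed. Of the 257 lower genes, 235 were measured there, 153 were below 0 and the median was -0.20 (p = 0.00111, and p = 0.319 with an estimated correlation) and 6 passed. In brain, 58 of 99 higher genes were above 0 with a median of 0.05 (p = 0.00153, and p = 0.128 with an estimated correlation) and 9 passed. Of 245 lower genes, 127 were below 0 there with a median of -0.03 (p = 0.373, and p = 0.828 with an estimated correlation) and 8 passed. Without brain EtOH replicate 3 and brain JHA replicate 1, brain-enriched genes in brain had a median of -0.18 with 20E (camera, adjusted p = 1.01e-06 with the preset correlation and 0.295 with an estimated one). With all libraries it was -0.02 (adjusted p = 0.861 with the preset correlation, 0.971 with an estimated one and 0.982 with fry). The 2 removed libraries had the lowest shares of these genes, 11.9% and 11.1%. Removing the solvent library among them raises the solvent level and so pushes the median down.

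The rise from 0 to 370 ovary genes under 20E without these 2 libraries was weighed against 2 technical explanations. JHA replicate 1 is in neither group compared. On the first principal component, 20E replicate 3 lay on the far side of solvent from the other 20E libraries. Removing it can by itself widen the 20E difference. If RNA of fat body or brain had lowered the ovary-enriched share of the 2 libraries to 2.91% and 3.54%, from a mean of 5.78% in the other 7, it would make up 49.6% and 38.8% of them, and fat-body-enriched genes would reach 27% and 21.5% of counts. They stood at 2.74% and 2.63%, and the largest rise of either tissue's genes was 4.05% of the rise needed. This argues against such RNA as the source of the lower ovary-enriched share. Both values still lay above those of the other 7 libraries (mean 1.83%, SD 0.129), so a smaller amount of fat body RNA stays open. Whether such an amount would remove calls was not tested. Low depth is argued against by the depths themselves. JHA replicate 1 held 10.2 M (mega) gene counts and 20E replicate 3 held 12.6 M, while the shallowest ovary library was JHA replicate 3, at 9.74 M. After all 9 ovary libraries were thinned to 9.74 M each, 0 genes passed for 20E with all of them and 354 without the 2. A different state of these 2 ovaries, or RNA of a tissue not sampled, may still account for the rise in calls and was not tested.

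A second hypothesis is that part of the 20E response is shared between brain and fat body. The 10 splits of the numbers, made in the same way in both tissues, are too few for a share under 0.05; the real split gave 18 shared genes and the highest of the other splits 0. The correlation of 20E fold changes between the tissues was 0.361 for the real split and up to 0.349 for the others. Whether 1 ant set the shared calls stays open: their groups do not overlap, so the 18 keep their directions whichever number is left out, and between 4 and 15 of the 18 still passed in both tissues. Since the tissues of a treatment come from the same 3 ants, a chance difference between the ants of the 2 groups could enter both.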
